A study of Homo sapiens with 9 samples.

How the data were processed

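RNA was sequenced from HCA2, a cell line of human foreskin fibroblasts, in 9 libraries. The normal group held 3 libraries of cells labelled proliferative, and senescent cells gave 3 libraries sorted as PD-L1-negative and 3 sorted as PD-L1-positive. PD-L1, the product of CD274, is the ligand of the inhibitory T cell receptor PD-1. Per the labels' protocols, the senescent cells received doxorubicin, a DNA-damaging drug, at 100 nM for 24 hours and then BI-2536, an inhibitor of the mitotic kinase PLK1, at 100 nM, which made up 12 days in total. The normal libraries carry the PD-L1 label positive, and no label says whether those cells were sorted. Per the labels' protocols, RNA was extracted with ISOGEN, polyA RNA was selected with beads, and libraries were made with a kit that keeps the strand. The labels do not say whether replicates were separate cultures, so every p-value measures the spread between these libraries, all from 1 line.

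The authors deposited FPKM values (fragments per kilobase of transcript, scaled to sequencing depth) as a table of 52741 RefSeq transcripts with 26196 gene symbols, of which 41012 transcripts had NM and 11729 had NR identifiers. Per the submitters' processing notes, STAR 2.5.2a, HTSeq 0.11.2, DESeq2 1.22.2 and genome build hg19 were used, without a statement of what each did. No header, label or note names the program that computed the FPKM. Between 49.1% and 50.3% of the values per library had up to 6 digits, and between 98.9% and 99.7% had these or a further 5, as the mean of a pair of rounded numbers would. Whether runs were averaged is not recorded. The authors also deposited an iRegulon table of motifs and ChIP-seq tracks with a normalized enrichment score (NES) for each. Per the file headers, it came from iRegulon version 1.3 with 9713 motifs, 1120 tracks, a minimum score of 3 and 223 valid input genes, and the headers do not say how these were chosen.

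The files held no counts, and FPKM depends on each transcript's length, so whole reads were not recovered and no count test was run. Depth was estimated from the smallest steps between low FPKM values of 7210 genes with 1 listed transcript of 1500 to 6000 bases, which gave 11500000 to 17500000 fragments per library with a median of 14500000. Transcript lengths came from a GRCh38 annotation, whereas the files use hg19, so no coordinates are given.

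Transcript FPKM were summed per gene symbol, and 12763 genes with a mean FPKM of at least 0.5 over the 9 libraries were tested. Differences were fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with an intensity trend and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Every log2 fold change is on the log2(FPKM + 0.5) scale, which understates changes of genes near 0. All 9 libraries entered 1 fit with 6 residual degrees of freedom, and 4 contrasts were taken: PD-L1-positive minus PD-L1-negative senescent, the mean of both senescent groups minus normal, and each senescent group minus normal. CD274 was also compared between pairs of groups with an exact two-sided permutation test, which cannot give a p below 0.1 for 3 against 3 libraries. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

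The groups, contrasts, tests, filter, pseudocount, 35 gene lists, rule for naming genes and most alternatives were fixed before the data were examined. Lists with at least 5 tested members, 29 in all, were tested with camera from limma at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Camera compares a list with the other genes, and fry asks whether the list's own genes move on balance in 1 direction. The genes named were CD274, CDKN1A, CDKN2A, LMNB1, MKI67 and IL6; the 4 members with the lowest p in each described list; and the 5 largest rises and 5 largest falls among called genes whose libraries did not overlap, without names that are only clone or locus identifiers, XIST and Y-linked genes. Lists described were the 8 with the lowest camera p under the threshold, 3 more fixed for every contrast, and the cell-type lists as levels. In the closing observations the same rule was applied to the remaining lists, a choice made after the values were seen. Members that moved against their list were also picked after their values were seen.

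Alternatives covered the pseudocount (0.1 and 1), the filter, median-of-ratios, quantile and scaling of each library to an equal sum, the intensity trend, sample weights, a replicate block, stricter thresholds, only the libraries compared, and leaving out each library in turn. After the data were seen, fits without small RNA genes, with NM genes only and with transcripts in place of genes were added. The number of genes called was also counted over all 84 splits of 9 libraries into 6 and 3 and over all 10 splits of 6 into 3 and 3. For the iRegulon targets, medians were set against 10000 random lists matched over 20 bins of mean expression. The fit was tested on simulated normal values with each gene's mean in the senescent libraries and its residual spread, in 3 runs with 200 changed genes among 12763. For PD-L1-positive minus PD-L1-negative it recovered 22.9%, 76.6% and 93.4% of genes changed by 0.5, 1 and 2 on the log2 scale, with 14 false calls in all, and for senescent minus normal 38.3%, 81.6% and 94.4%, with 15. In 20 simulated runs for PD-L1-positive minus PD-L1-negative with 1 list moved by 0.3 on the log2 scale, camera called the moved list 20 times and made 4 other calls over 29 lists. Values simulated from each gene's mean and spread do not model correlation between genes, which was estimated at 0.953 for the mitosis list. These counts therefore do not show how often camera calls correlated lists wrongly.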

Results

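Messenger RNA was measured in 3 libraries each of normal, senescent PD-L1-negative and senescent PD-L1-positive HCA2 fibroblasts, at an estimated 11500000 to 17500000 fragments per library. Between 11437 and 11891 genes reached an FPKM of 1 in each library. Dermal fibroblast markers were abundant, with median FPKM of 57.9 in normal, 70.3 in PD-L1-negative and 69.5 in PD-L1-positive cells, and VIM, a mesenchymal intermediate filament, averaged 2390. Markers of keratinocytes, melanocytes, endothelial cells and leukocytes had medians of at most 0.0523 in every group, although single members such as FLT1 (28.6), KRT10 (15.4) and MITF (9.06) were expressed. Pericyte markers had medians of 3.29, 3.22 and 3.54.

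The 3 normal libraries differed from one another in proliferation. MKI67, a marker of cycling cells, was 61.3, 33.4 and 12.7 FPKM in normal replicates 1, 2 and 3, and CDKN1A, which encodes the cell cycle inhibitor p21, was 110, 214 and 311. Correlations across genes, which are not independent replicates, were 0.951 to 0.980 within the normal group and 0.9745 to 0.9882 among the 6 senescent libraries, within and between fractions. The first principal component held 65% of the variance and placed the normal libraries at −71.7, −53.8 and −32.1 and the senescent ones at 24.3 to 29.9. Small RNA genes took 14.86% of the FPKM in PD-L1-positive replicate 3 and at most 6.57% elsewhere. MIR6723, counted among them, and the MTRNR2L genes, which were not, together took 11.74% in that library and 0.44% to 3.59% elsewhere.

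The CD274 transcript level checked the sort at the level of RNA. CD274 averaged 1.31 ± 0.0738 FPKM (SD, n = 3) in PD-L1-positive and 0.765 ± 0.126 (n = 3) in PD-L1-negative senescent cells, a ratio of 1.71, and 4.20 ± 1.78 (n = 3) in normal cells. The main transcript, NM_014143, averaged 1.31 ± 0.0737, 0.523 ± 0.174 and 4.0 ± 1.89 in these groups, a ratio of 2.5 between the sorted fractions. No library of one group overlapped another group, and the exact two-sided permutation p was 0.1 for each pair with n = 3, the smallest the design allows. In the fit over all genes CD274 fell from normal to senescent cells by 1.57 on the log2 scale (SE 0.20, adjusted p = 0.000237). Between the fractions the log2 difference was 0.52 (SE 0.23, adjusted p = 1), and 0.84 (SE 0.30, 95% interval 0.17 to 1.51, adjusted p = 1) for the main transcript. The transcript rested on about 17 to 30 fragments per PD-L1-negative, 58 to 79 per PD-L1-positive and 128 to 390 per normal library. The other 2 listed transcripts had 8 values of exactly 0, so their split of the gene's reads is uncertain.

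**Figure D1:**
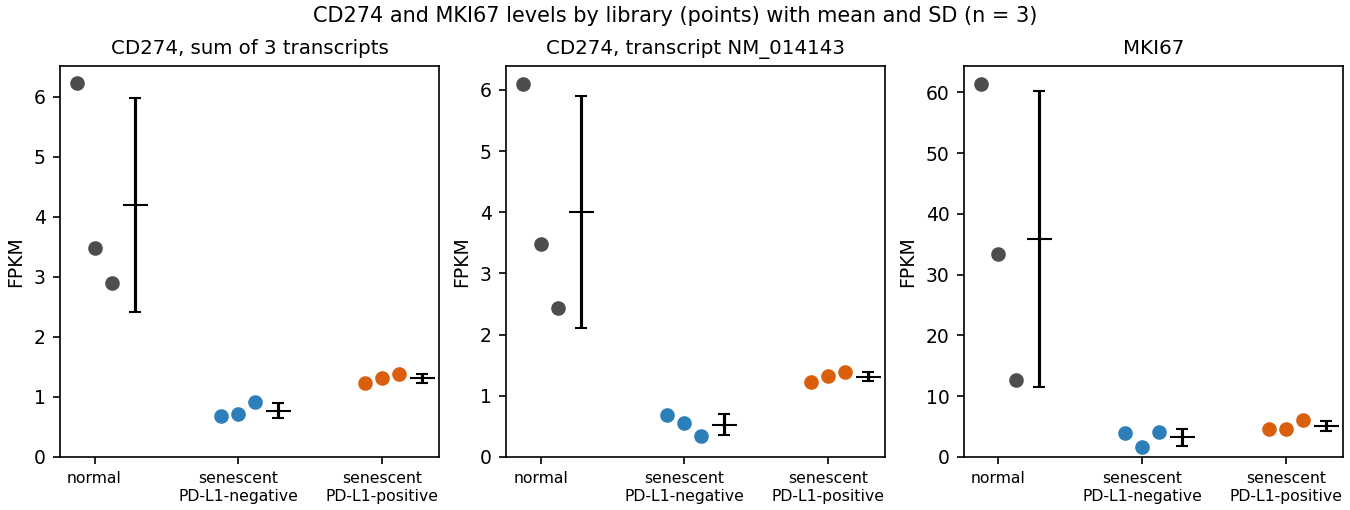
FPKM of CD274 (sum of 3 transcripts), of CD274 transcript NM_014143 and of MKI67 in each library (points) by group, with mean and SD (n = 3). CD274 was 2.89 to 6.23 in normal, 0.677 to 0.909 in PD-L1-negative and 1.23 to 1.38 in PD-L1-positive libraries, and MKI67 was 12.7 to 61.3 in normal libraries.

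Senescent cells were compared with normal cells to describe the state that followed doxorubicin and BI-2536. Of mitosis genes 40 of 40 fell and of DNA replication genes 42 of 43, while 26 of 35 lysosomal genes, 12 of 14 histone transcripts, 24 of 33 secreted proteases, inhibitors and growth factors and 14 of 21 secreted cytokines and chemokines rose. Adjusted over each list alone the counts were equal but for 28 lysosomal genes. No list kept its camera call with an estimated correlation, where the lowest value was adjusted p = 0.316, while fry called 23 of 29 lists. MKI67 fell from 35.8 ± 24.4 FPKM (SD, n = 3) to 4.14 ± 1.45 (n = 6), and LMNB1, the nuclear lamina protein lamin B1, fell from 42.0 ± 23.1 to 4.04 ± 0.879 (log2 −3.08, SE 0.32, adjusted p = 9.36e-05). CDKN1A rose from 212 ± 101 to 556 ± 70.4 (SE 0.26 on the log2 scale, adjusted p = 0.00124), and IL6, a secreted inflammatory cytokine, rose from 150 ± 90.6 to 365 ± 38.4 (log2 1.46, SE 0.32, adjusted p = 0.00386). CDKN2A, which encodes the inhibitor p16 among other products, measured 11.1 ± 1.83 and 13.6 ± 1.97 (adjusted p = 0.13). This is the sum of its transcripts, so the p16 transcript was not measured alone. Of 12763 genes, limma called 3044 higher and 3821 lower in senescent cells, 739 and 767 of them with an absolute log2 fold change of at least 1. The libraries of the groups did not overlap for 48.73% of genes, against 2.38% by chance. The SD exceeded 0.5 on the log2 scale for 1271 genes in normal, 280 in PD-L1-negative and 441 in PD-L1-positive libraries. The fit pooled these spreads, which can make p-values against the more variable normal cells too low. The senescent and normal groups differed in drug exposure, BI-2536 and time together. Both senescent groups were also sorted for PD-L1, and no label says whether the normal cells were. The effects of these cannot be separated.

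All 40 mitosis genes fell, over all genes and adjusted over the list alone, with a median log2 change of −2.10 (camera adjusted p = 1.24e-10, and adjusted p = 0.469 with an estimated correlation). FOXM1, a transcription factor of mitotic genes, fell from 58.5 ± 25.5 to 10.3 ± 3.03 FPKM, the kinase AURKB by 2.57, the kinesin KIF20A by 2.65 and the cyclin CCNA2 by 2.74 on the log2 scale. Of 43 DNA replication genes 42 fell and 1 rose, likewise adjusted over the list alone, with a median of −1.58 (adjusted p = 1.24e-10, and adjusted p = 0.469 with an estimated correlation). Thymidine kinase TK1 fell from 111 ± 33.2 to 22.3 ± 2.70, and the replication helicase genes CDC45, GINS2 and MCM5 fell by 2.42, 2.45 and 2.34 on the log2 scale. The member that rose was CCNE1, a cyclin of the entry into S phase (log2 0.72, adjusted p = 0.00465). Of 24 genes of homologous recombination and the Fanconi pathway, which repair DNA breaks and crosslinks, 22 fell by either adjustment, adjusted over the list alone included, with a median of −1.48 (adjusted p = 2.74e-06, and adjusted p = 0.496 with an estimated correlation). BRIP1, BARD1, FANCA and EXO1 fell by 1.72, 1.67, 1.75 and 1.93.

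Among proteases, inhibitors and growth factors of the senescence-associated secretory phenotype (SASP), 24 of 33 tested genes rose and 2 fell, or 24 and 3 adjusted over the list alone, with a median of 1.27 (camera adjusted p = 1.86e-08, and adjusted p = 0.316 with an estimated correlation). Tissue plasminogen activator PLAT rose from 24.9 ± 2.25 to 174 ± 21 FPKM (log2 2.78, SE 0.10, adjusted p = 1.19e-06). The growth factor EREG rose from 2.31 to 10.7, and the insulin-like growth factor binding proteins IGFBP2 and IGFBP6 rose from 9.40 to 77.4 and from 171 to 725. TGFB1 (log2 −0.31) and NRG1 (log2 −1.49), both growth factors, fell. Among SASP cytokines and chemokines, 14 of 21 rose and 2 fell by both adjustments, adjusted over the list alone included, with a median of 1.12 (adjusted p = 0.00123, and adjusted p = 0.316 with an estimated correlation). CXCL6, a neutrophil chemokine, rose from 7.64 to 90.9, CCL2 from 129 to 369 and IL1B from 7.96 to 19.4. CXCL12 fell from 318 ± 65.7 to 72.9 ± 20.5, and CXCL8, another neutrophil chemokine, fell by 0.37 on the log2 scale (adjusted p = 0.0327).

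NF-kB targets rose in 17 of 28 cases and fell in 1, or 18 and 1 adjusted over the list alone, with a median of 1.01 (camera adjusted p = 2.33e-06, and adjusted p = 0.369 with an estimated correlation). NFKBIA, the inhibitor of NF-kB, rose from 38.5 ± 1.05 to 119 ± 7.65, complement C3 from 4.78 ± 2.25 to 107 ± 9.54 (log2 4.43, SE 0.21, adjusted p = 2.78e-06), TNFAIP3 from 5.81 to 28.5 and the mitochondrial dismutase SOD2 from 78.1 to 449. The member that fell was BIRC2, an inhibitor of apoptosis (log2 −0.35). Targets of p53 rose in 17 of 32 cases and fell in 1, adjusted over the list alone too, with a median of 0.56 (adjusted p = 0.000271, and adjusted p = 0.469 with an estimated correlation). RRM2B, a ribonucleotide reductase subunit, rose from 8.04 to 24.3, TP53INP1 from 1.96 to 7.03, MDM2, which encodes the p53 ubiquitin ligase, from 12.9 to 27.9 and the antiproliferative gene BTG2 from 5.14 to 37.3. AEN, a nuclease gene, fell by 0.66 on the log2 scale.

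Lysosomal genes rose in 26 of 35 cases and fell in 3, or 28 and 3 adjusted over the list alone, with a median of 0.52 (camera adjusted p = 7.89e-08, and adjusted p = 0.402 with an estimated correlation). PSAP rose from 170 to 501 FPKM, the mannosidase MANBA from 4.38 to 18.5 and cathepsin CTSF from 4.26 to 16.6. PPT1, a palmitoyl thioesterase, fell from 38.1 ± 1.11 to 11.3 ± 0.619, and GUSB and CLN3 fell as well. Proteasome subunits fell in 26 of 33 cases and 28 adjusted over the list alone, and none rose, with a median of −0.51 (adjusted p = 6.74e-08, and adjusted p = 0.469 with an estimated correlation). PSMC3 fell from 123 to 59.4, PSMA7 from 200 to 114, and PSMD12 and PSMD11 by 0.69 and 0.72 on the log2 scale. Transcripts of replication-dependent histones rose in 12 of 14 cases and fell in 2, adjusted over the list alone too, with a median of 2.06 (adjusted p = 6.36e-06, and adjusted p = 0.316 with an estimated correlation). HIST1H2AC rose from 7.78 ± 3.39 to 82.3 ± 12.4, HIST1H2BD from 4.87 to 42.1, HIST1H4H from 0.639 to 17.8 and HIST2H2BE from 2.16 to 18.8, whereas HIST1H4C and HIST2H2AC fell by 1.41 and 1.64 on the log2 scale. Only 14 of 20 listed histone genes passed the filter. PolyA RNA was selected, so the values cover only the histone messages that this selection kept.

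Co-inhibitory and co-stimulatory ligands moved both ways: 5 of 17 rose and 6 fell, or 6 and 6 adjusted over the list alone. CD274 was among those that fell, with BTN2A1 (18.7 to 11.9 FPKM) and BTN3A2 (7.19 to 4.72), both butyrophilins, and CD47, a signal against phagocytosis, rose from 15.4 to 20.8. The list's median was −0.03, its mean 0.01 and camera's direction upward (adjusted p = 0.982, and adjusted p = 0.99 with an estimated correlation). The largest rises were those of SNORA70, a small nucleolar RNA that was listed at 0, 0 and 27.5 FPKM in the normal libraries and at 30.7 to 150 in the senescent ones; TXNIP, an inhibitor of thioredoxin (2.15 to 62.9); C3; HIST1H4H; and the prostacyclin synthase PTGIS (8.30 to 115). The largest falls were those of the keratin KRT81 (9.74 to 0.480), CRIP1 (42.4 to 4.07), the E2F-regulated factor MYBL2 (31.7 to 2.92), cardiac actin ACTC1 (5.90 to 0.212) and LMNB1.

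**Figure D2:**
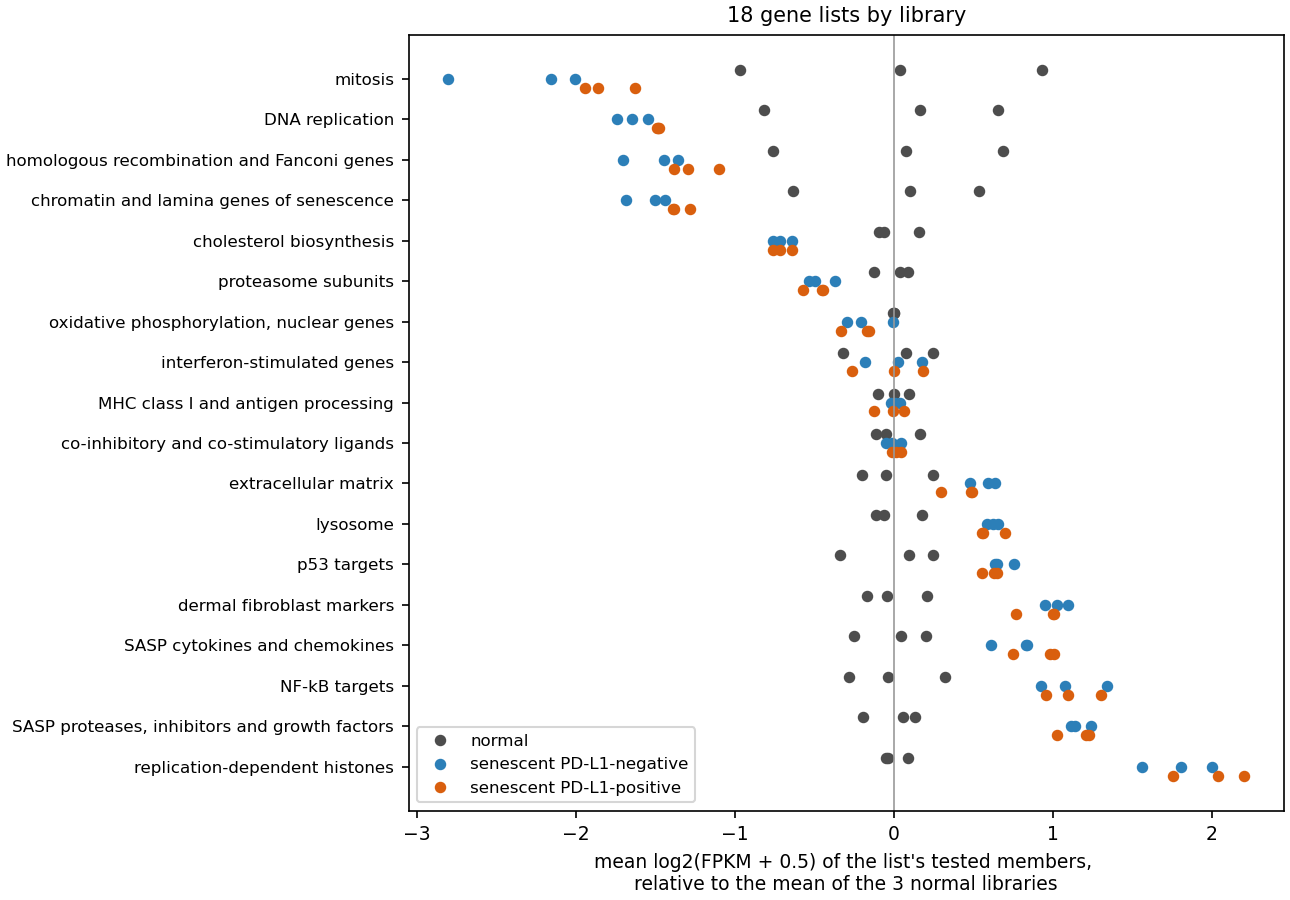
Mean log2(FPKM + 0.5) of the tested members of 18 gene lists in each library (points), relative to the mean of the 3 normal libraries, with groups by color. The mitosis list spanned 1.90 among the normal libraries, and all 6 senescent libraries lay lower for mitosis and higher for histones than every normal library.

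Each sorted fraction was also compared with the normal cells. In PD-L1-negative cells the mitosis list had a median log2 change of −2.42 and all 40 members fell; in PD-L1-positive cells the median was −1.80 and 38 fell, or 39 adjusted over the list alone (camera adjusted p = 1.08e-11 and 3.64e-09, and adjusted p = 0.465 and 0.495 with an estimated correlation). MKI67 fell to 3.21 ± 1.36 and 5.08 ± 0.879 FPKM (n = 3 each), LMNB1 to 3.45 ± 0.878 and 4.63 ± 0.350, and the ubiquitin-conjugating enzyme gene UBE2C fell from 104 ± 74.3 to 11.9 ± 0.835 and 21.8 ± 2. CDKN1A rose to 603 ± 74.9 and 509 ± 13.5, and IL6 to 368 ± 32.7 and 362 ± 50.9. CD274 fell by 1.83 (SE 0.23, adjusted p = 0.000356) in PD-L1-negative and by 1.31 (SE 0.23, adjusted p = 0.00177) in PD-L1-positive cells. CDKN2A measured 13.5 ± 2.39 and 13.7 ± 1.99 (adjusted p = 0.217 and 0.176).

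The PD-L1-negative fraction had 2674 genes higher and 3392 lower than normal cells, and the PD-L1-positive fraction 2696 and 3362. In the PD-L1-negative fraction 42 DNA replication genes fell and CCNE1 rose, and in the PD-L1-positive fraction 41 fell, or 42 adjusted over the list alone, and CCNE1 rose (medians −1.64 and −1.46, adjusted p = 3.24e-11 and 6.7e-10, and adjusted p = 0.465 and 0.495 with an estimated correlation). Genes of homologous recombination and the Fanconi pathway fell in 21 and 20 of 24 cases, or 22 and 21 adjusted over the list alone, with medians of −1.63 and −1.39 (adjusted p = 1.11e-06 and 1.07e-05, and adjusted p = 0.465 and 0.495 with an estimated correlation). Proteasome subunits fell in 26 and 27 of 33 cases, or 27 and 27 adjusted over the list alone (medians −0.50 and −0.53). Lysosomal genes rose in 26 and 25 of 35 cases and fell in 3 and 3, or rose in 26 and 29 adjusted over the list alone, and PPT1 fell to 11.1 ± 0.131 and 11.5 ± 0.912. NF-kB targets rose in 17 and 15 of 28 cases, or 17 and 18 adjusted over the list alone, with C3 at 103 ± 10.8 and 112 ± 6.67 and NFKBIA at 121 ± 8.34 and 117 ± 8.2. Targets of p53 rose in 15 and 16 of 32 cases and AEN fell, likewise adjusted over the list alone (medians 0.54 and 0.57). Chromatin and lamina genes fell in 15 and 15 of 17 cases, or 16 and 15 adjusted over the list alone (medians −1.70 and −1.41), and histones rose in 12 and 12 of 14 and fell in 1 and 2, adjusted over the list alone too (medians 2.06 and 2.10).

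SASP proteases, inhibitors and growth factors rose in 24 of 33 cases and fell in 2 in each fraction, or rose in 24 and 25 and fell in 2 and 3 adjusted over the list alone (medians 1.34 and 1.16, adjusted p = 2.09e-08 and 5.24e-09, and adjusted p = 0.336 and 0.26 with an estimated correlation); IGFBP2 averaged 83.7 ± 11.6 and 71.0 ± 11, and PLAT 163 ± 15.9 and 186 ± 21. SASP cytokines rose in 13 of 21 cases and fell in 2 in PD-L1-negative cells and rose in 14 and fell in 1 in PD-L1-positive cells, or fell in 2 adjusted over the list alone (medians 1.02 and 1.24, adjusted p = 0.00333 and 0.000419, and adjusted p = 0.359 and 0.26 with an estimated correlation). Co-inhibitory and co-stimulatory ligands rose in 5 of 17 cases and fell in 5 in each fraction, adjusted over the list alone too (adjusted p = 0.977 and 0.973). In PD-L1-negative and PD-L1-positive cells CCL7, a monocyte chemokine, rose from 0.415 to 4.23 and 4.25, CSF3, a granulocyte growth factor, from 1.46 to 3.60 and 5.54, C10orf54, which encodes the checkpoint ligand VISTA, from 4.70 to 13.6 and 10.7, and BTN2A2 from 3.24 to 4.62 and 4.95. The largest changes repeated those above, with a rise of TNXB, a matrix glycoprotein (0.362 to 13.1 in PD-L1-negative and 8.78 in PD-L1-positive cells), and falls of SAMD11 (19.8 to 3.03 and 1.86) and the oxytocin receptor OXTR (120 to 14.4 and 15.5). MIR6753 was listed at 0 in all 3 PD-L1-negative libraries, at 6.66, 0 and 13.9 in the PD-L1-positive ones and at 6.43, 5.94 and 14.1 in the normal ones. SNORA70 passed the test in both comparisons, but not without normal replicate 1 or 2 (adjusted p = 0.0571 and 0.0671 for PD-L1-negative, 0.0566 and 0.0664 for PD-L1-positive), PD-L1-negative replicate 2 (0.0662) for the first, or PD-L1-positive replicate 3 (0.0571) for the second. Every list called in either comparison lost its call with an estimated correlation, where the lowest values were adjusted p = 0.336 for PD-L1-negative and adjusted p = 0.26 for PD-L1-positive cells, while fry called 21 of 29 lists in each. Both comparisons used the same normal libraries, so whether the fractions differ was tested only by the contrast between them.

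The contrast between the sorted fractions asked which genes go with surface PD-L1 in senescent cells. No gene passed the test: limma called 0 of 12763, with 222 genes at an unadjusted p under 0.05 where chance gives 638, and a smallest unadjusted p of 0.000112. The fit pooled the spread of all 9 libraries, and the normal ones varied more. Their median SD was 0.184 on the log2 scale, against 0.137 in PD-L1-negative and 0.125 in PD-L1-positive libraries. Pooling can raise p-values between the fractions, so the deficit below 638 does not measure how alike the fractions are. With only the libraries compared, RNF5 alone was called (limma adjusted p = 0.0491). The libraries did not overlap for 9.42% of genes, against 10% by chance. MKI67 measured 3.21 ± 1.36 FPKM (SD, n = 3) in PD-L1-negative and 5.08 ± 0.879 (n = 3) in PD-L1-positive cells, CDKN1A 603 ± 74.9 and 509 ± 13.5, IL6 368 ± 32.7 and 362 ± 50.9, LMNB1 3.45 ± 0.878 and 4.63 ± 0.350, and CDKN2A 13.5 ± 2.39 and 13.7 ± 1.99, all with adjusted p = 1.

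Mitosis genes stood out as a list. All 40 had a positive difference in PD-L1-positive cells, with a median of 0.52 on the log2 scale and 0 called singly, adjusted over the list alone or not (camera adjusted p = 4.08e-12, and adjusted p = 0.913 with an estimated correlation). The estimated correlation, 0.953 for this list, came from the residuals of all 9 libraries, the normal ones included. The list mean was 2.99, 2.34 and 3.14 in the PD-L1-negative and 3.28, 3.20 and 3.52 in the PD-L1-positive libraries on the log2 scale. UBE2C measured 11.9 ± 0.835 in PD-L1-negative and 21.8 ± 2 in PD-L1-positive cells, the kinase CDK1 6.52 and 11.3, topoisomerase TOP2A 14.7 and 24.4, and PTTG1, the securin of sister chromatids, 28.1 and 40.8. Other lists had smaller positive medians. These were homologous recombination and Fanconi genes (22 of 24 positive, median 0.26, adjusted p = 0.00629), DNA replication (36 of 43, 0.14, 0.0196), chromatin and lamina genes (17 of 17, 0.17, 0.0226) and histones (11 of 14, 0.14, 0.0302), each with adjusted p = 0.913 with an estimated correlation. As a list, histones were higher in senescent than in normal cells (median 2.06), whereas the other lists named here were lower. The positive difference of the histone list therefore pointed away from normal cells. XRCC3 measured 2.67 and 4.66, FANCA 1.53 and 2.26, RRM2 14.2 and 21.2, TK1 20.1 and 24.4, the methyltransferase EZH2 2.79 and 3.96, and HIST1H2BC 11.7 and 17.9. HIST2H2AC was listed at 0 in the 3 PD-L1-negative libraries and at 0.540, 0.986 and 0.364 in the PD-L1-positive ones, and passed when adjusted over the list alone (0.0221).

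SASP cytokines and chemokines had 15 of 21 positive differences and a median of 0.12 (camera adjusted p = 0.0237, and adjusted p = 0.913 with an estimated correlation). Without PD-L1-negative replicate 2, PD-L1-positive replicate 1 or PD-L1-positive replicate 3 the adjusted p was 0.341, 0.338 or 0.0807. CSF3 measured 3.60 ± 0.657 and 5.54 ± 0.417, CCL5 1.71 and 3.94, IL1B 16.8 and 22, and CXCL5 5.50 and 7.85. Extracellular matrix genes had 13 of 36 positive differences and a median of −0.10 (adjusted p = 0.00631, and adjusted p = 0.913 with an estimated correlation): COL3A1 measured 345 ± 12.1 and 276 ± 21.2, periostin POSTN 27.0 and 18.8, decorin DCN 725 and 521, and COL15A1 14.6 and 8.11. Nuclear genes of oxidative phosphorylation had 7 of 35 positive differences and a median of −0.05 (adjusted p = 0.0218, and adjusted p = 0.913 with an estimated correlation), with COX7C at 332 and 286, UQCRB at 22.3 and 19.7, NDUFA4 at 34.1 and 30.7, and COX6C at 53.8 and 49.9.

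Of 17 co-inhibitory and co-stimulatory ligands, CD274 included, 0 were called, adjusted over the list alone or not (list median 0.01, adjusted p = 0.85, and adjusted p = 0.935 with an estimated correlation), with TNFSF9 at 0.511 and 0.379, PVR at 21.5 and 25.4, and BTN3A1 at 5.60 and 5.11. Targets of p53 had 9 of 32 positive differences and a median of −0.08 (adjusted p = 0.0871), with TNFRSF10A at 1.63 and 2.07, FBXO22 at 10.3 and 9.39, SERTAD1 at 36.9 and 31.1, and DDB2 at 18.3 and 16.3. Outside these lists, PLAU, the urokinase, measured 89.1 ± 4.95 and 125 ± 12.3, and LAPTM5, a leukocyte marker, 0.480 ± 0.0567 and 0.995 ± 0.221. Both passed only when adjusted over the list alone (0.0361 and 0.0157) and were picked after their values were seen. Camera called 8 of 29 lists, and 0 were called with an estimated correlation, where the smallest adjusted p was 0.913, or by fry. The mitosis list kept its camera call without each library in turn, but PD-L1-negative replicate 2 carried much of the difference: without it the median was 0.25 in place of 0.52 (adjusted p = 0.00457), and without any other senescent library it was 0.41 to 0.70. The other 7 lists lost their calls without at least 1 library. Without PD-L1-negative replicate 2 the adjusted p was 0.312 for homologous recombination and for DNA replication, 0.392 for chromatin, 0.341 for SASP cytokines and 0.341, with the direction turned, for oxidative phosphorylation. Without PD-L1-positive replicate 3 these were 0.114, 0.0655, 0.151, 0.0807 and, turned again, 0.913. Histones had 0.584 without PD-L1-negative replicate 3, and extracellular matrix 0.0614 without PD-L1-negative replicate 1.

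**Figure D3:**
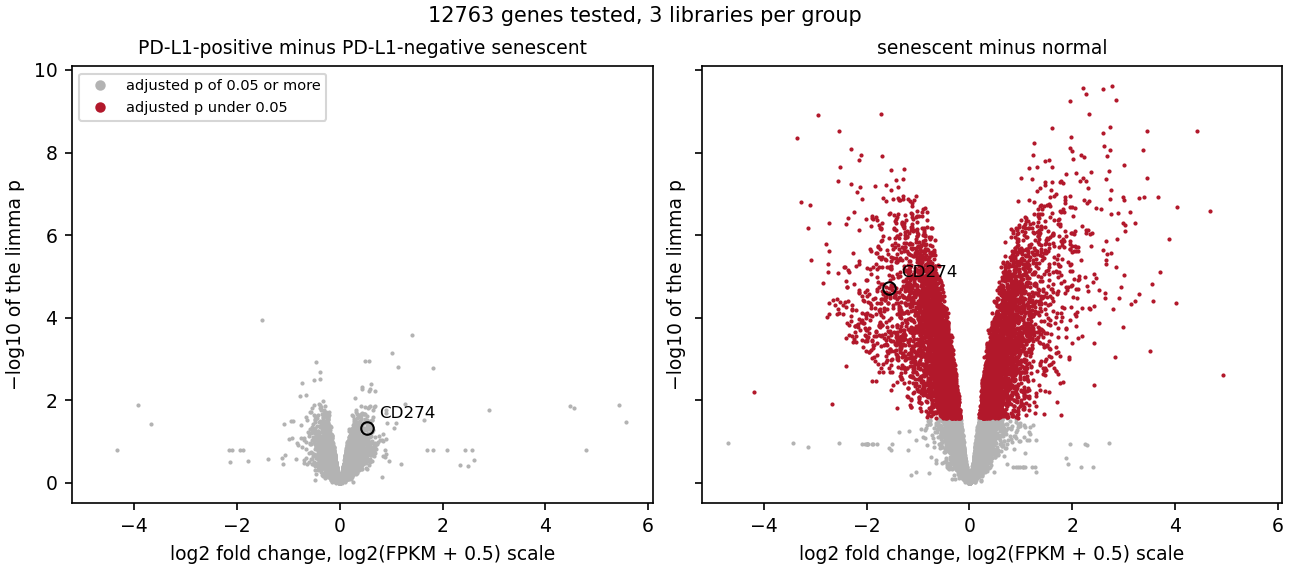
Log2 fold change against −log10 of the unadjusted limma p for 12763 genes between the sorted fractions (left) and between senescent and normal cells (right), with called genes in red and CD274 circled. Between the fractions 0 genes were called, with a smallest p of 0.000112, and between senescent and normal cells 6865 were.

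The authors' deposited iRegulon table described regulators of input genes that, by the aim the series names, may be those correlated with PD-L1. It held 112 motif entries, of which 46 named E2F or TFDP factors, regulators of the G1 to S transition, with NES up to 11.9, and 29 named NFY, with NES up to 7.61. Of 16 ChIP-seq tracks, 7 were of E2F or TFDP factors (NES up to 10.4), 5 of FOXM1 (8.36), 3 of SIN3A and 1 of MYBL2. No entry named a STAT or IRF factor, NFKB1, RELA, RELB or a JUN or FOS factor, 1 motif entry named BATF3 of the AP-1 family (NES 3.06), and 27 motif entries named no factor. The entries listed 210 targets, CD274 among them, and 209 were tested. From normal to senescent cells all 209 fell, with a median of −1.52, and 209 and 203 fell in PD-L1-negative and PD-L1-positive cells. Between the fractions 0 targets were called, 198 differences were positive and 11 negative, and the median was 0.23. All 10000 random lists had a lower median, which carries no weight, because the targets followed CD274 over these same libraries and random lists lack the correlation among cell cycle genes.

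The deposited list was not independent of these libraries. All 210 targets, of which CD274 does so by construction, had a squared correlation of at least 0.95 with CD274 transcript NM_014143 over the 9 libraries, counting each gene by its best transcript, and 223 genes reached that value, the number of valid input genes in the file header. This rule was found after the table was seen, when an unsquared correlation of 0.95 had given 765 genes. The authors' name for the table includes R0.95, which may state a threshold of 0.95. Beyond that name, how the authors chose the list is not recorded. Because normal and senescent libraries form separate clusters, that relation is given only to describe how the list may have arisen. Within the 6 senescent libraries 0 of the 209 targets other than CD274 itself reached a squared correlation of 0.95, and 203 had a positive correlation. The count of 203 carries no weight, because the targets followed CD274 over libraries that include these 6. The share of all genes with a positive correlation is not given. As 0 genes were called between the fractions, 0 were called both there and between senescent and normal cells, and the overlap of these independent contrasts could not be tested.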

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

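Between the sorted fractions the number of genes called stayed at 0 or close to it. It was 1 higher and 1 lower with no filter (HIST1H2BB and LINC01340), 2 higher with transcripts in place of genes (of CDV3 and PKM), an alternative chosen after the data were seen, and 1 lower with a pseudocount of 0.1, with sample weights and with only the libraries compared, each time RNF5. Leaving out each library in turn gave 0 to 3 higher and 0 to 1 lower, mostly small RNA genes such as SNORA11 and SNORD89. RNF5 averaged 0.939 FPKM in PD-L1-negative cells and was listed at 0 in PD-L1-positive cells. With a pseudocount of 0.1, 1 gene was called both between the fractions and between senescent and normal cells, against 0.538 by chance. The causes were not tested.

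Between senescent and normal cells 739 genes were higher and 767 lower with an absolute log2 fold change of at least 1. At an adjusted p under 0.01, 1661 and 2139 genes were called for PD-L1-negative and 1665 and 2069 for PD-L1-positive cells against normal cells, and 742 and 802, and 752 and 757, with that fold change. Scaling each library to an equal sum moved the median of all genes between senescent and normal cells from −0.04 to −0.16 and the share of called genes that were higher from 44.3% to 33.5%. Directions of single genes with small changes depend on this choice. CD274 kept its sign and its calls throughout.

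Gene list calls depended on the correlation assumed between genes. With an estimated correlation 0 lists were higher and 0 lower in each of the 4 comparisons. With fry in place of camera, which does not set a list against the other genes, 0 and 0 were called between the fractions, 11 higher and 12 lower between senescent and normal cells, and 10 and 11, and 9 and 12, for PD-L1-negative and PD-L1-positive against normal cells. Between the fractions quantile normalization left 0 lists lower, and leaving out each library gave 2 to 6 higher and 1 to 4 lower. The oxidative phosphorylation list ranged from an adjusted p of 4.23e-07 to 0.913 when each library was left out, and its direction turned without PD-L1-negative replicate 2 (0.341) and PD-L1-positive replicate 3 (0.913). Targets of p53, not called otherwise, were called lower without normal replicate 1 (0.0233) and normal replicate 3 (0.0489). Leaving out a normal library changes only the spread that the fit uses, and not the differences between the fractions. Why the other calls changed was not tested.

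The differences of CDKN2A and IL6 and the direction of the ligand list changed sign in some alternatives, and did not pass the test there. For CDKN2A between the fractions the log2 difference ranged from −0.121 to 0.147 when each library was left out, with −0.011 and −0.05 without PD-L1-positive replicates 1 and 3. For IL6 it ranged from −0.103 to 0.092, with 0.035 without PD-L1-negative replicate 1, and was 0 with quantile normalization. The direction of co-inhibitory and co-stimulatory ligands turned between the fractions without PD-L1-negative replicate 1 and PD-L1-positive replicate 2 (adjusted p = 0.928 and 0.94, range 0.639 to 0.94). Between senescent and normal cells it turned with quantile normalization (0.972), with fry (0.184) and without normal replicates 1 and 2 (0.753 and 0.939, range 0.563 to 0.993). For PD-L1-negative against normal cells the same alternatives gave 0.95, 0.249, 0.756 and 0.901, with 0.983 without PD-L1-negative replicate 3 (range 0.598 to 0.99). For PD-L1-positive against normal cells they gave 0.98, 0.265, 0.728 and 0.919, with 0.977 without PD-L1-positive replicate 2 (range 0.546 to 0.977). The cause was not tested.

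With the replicate number as a block, 0 genes were higher and 0 lower between the fractions, and 3199 and 3956 between senescent and normal cells. Against normal cells it called 2837 and 3515 for PD-L1-negative and 2861 and 3469 for PD-L1-positive cells. The block spanned all 9 libraries, the normal ones included. These counts therefore do not show what pairing only the sorted fractions would change. After group means were removed, PD-L1-positive and PD-L1-negative libraries of the same number correlated at 0.09, 0.22 and 0.46. Each PD-L1-negative library correlated best with the PD-L1-positive library of its own number, as did PD-L1-positive replicates 2 and 3, whereas PD-L1-positive replicate 1 correlated best with PD-L1-negative replicate 2 (0.14). This is a hint of pairing from the data and not from the design, and with 1 correlation under 0.1 the numbers were not taken to pair the libraries. The block left 6 lists higher and 2 lower between the fractions. The tests by edgeR and DESeq2 were not run, as the values used were FPKM and whole reads could not be recovered from them.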

Other observations

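Lists not described so far also differed between senescent and normal cells, and these genes were picked by the rule for named genes after the values were seen. Of 17 chromatin and lamina genes 15 fell, or 16 adjusted over the list alone (median −1.53, camera adjusted p = 8.28e-06, and adjusted p = 0.469 with an estimated correlation), with HMGB1 falling from 163 to 48.0 FPKM, LBR from 20.6 to 4.93 and EZH2 from 18.7 to 3.37. Cholesterol biosynthesis genes fell in 18 of 23 cases and rose in 1, TM7SF2, adjusted over the list alone too (median −0.62, adjusted p = 1.73e-05, and adjusted p = 0.369 with an estimated correlation), with MVK from 6.16 to 2.06 and EBP from 22.8 to 7.99. Sensors of cytosolic DNA and RNA fell in 9 of 15 cases, adjusted over the list alone too (median −0.40, adjusted p = 0.00991, and adjusted p = 0.469 with an estimated correlation): TMEM173, which encodes STING, fell from 32.9 to 11.3 and MB21D1, which encodes cGAS, from 5.17 to 1.72. Dermal fibroblast markers rose in 10 of 16 cases, adjusted over the list alone too (median 0.79, adjusted p = 0.000271, and adjusted p = 0.316 with an estimated correlation), with DPP4 from 7.93 to 86.0 and FBLN1 from 158 to 870. Extracellular matrix genes rose in 20 of 36 cases and fell in 4, among them COL6A3 and BGN, adjusted over the list alone too (adjusted p = 0.00111, and adjusted p = 0.469 with an estimated correlation), and MFAP5 rose from 10.7 to 22.

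Lists with weaker calls lost them without at least 1 library or with another scaling. Immediate early and AP-1 genes rose in 8 of 26 cases and fell in 2, or 7 and 2 adjusted over the list alone, with KLF6 falling from 50 to 25 and rises of ATF3 from 21.9 to 86.1 and JUN from 30.4 to 56.3 (camera adjusted p = 0.0118, 0.19 without normal replicate 1, and adjusted p = 0.615 with an estimated correlation). Interferon-gamma-responsive genes rose in 8 of 19 cases and fell in 2, adjusted over the list alone too, with IRF1 from 5.87 to 24.1 and GBP1 falling from 21.7 to 5.23 (adjusted p = 0.0327, 0.091 without normal replicate 1, and adjusted p = 0.513 with an estimated correlation). Glycolysis and hypoxia genes rose in 13 of 27 cases and fell in 2, adjusted over the list alone too (adjusted p = 0.0301, 0.0848 with quantile normalization, and adjusted p = 0.521 with an estimated correlation), with PFKP falling from 85.7 to 30.5, ENO1 falling from 763 to 322 and ADM rising from 110 to 272. Oxidative phosphorylation genes fell in 15 of 35 cases and rose in 1, COX4I1, adjusted over the list alone too (adjusted p = 0.0301, 0.0925 without normal replicate 3, and adjusted p = 0.653 with an estimated correlation), and NDUFA9 fell from 39.5 to 20.5. Heat shock genes fell in 6 of 12 cases and rose in 1, DNAJB1, or fell in 8 and rose in 1 adjusted over the list alone (adjusted p = 0.0352, 0.0511 without PD-L1-negative replicate 1, and adjusted p = 0.469 with an estimated correlation), with HSPD1 from 188 to 99.7. JAK-STAT genes rose in 9 of 22 cases and fell in 3, or 11 and 3 adjusted over the list alone (adjusted p = 0.0492, 0.119 without normal replicate 1, 0.0597 with median-of-ratios scaling, 0.0703 with quantile normalization, and adjusted p = 0.583 with an estimated correlation), with SOCS2 falling from 21.1 to 5.78 and IL6ST rising from 59.4 to 125. Lists that camera did not call included interferon-stimulated genes (8 of 37 rose and 5 fell, adjusted over the list alone too, adjusted p = 0.71; OAS3 fell from 7.42 to 1.02 and LGALS3BP rose from 15.2 to 31.9), MHC class I genes (6 of 21 rose and 8 fell, or 6 and 9 adjusted over the list alone, 0.982; B2M rose from 761 to 1410) and ligands of NK cell receptors (0 of 9 rose and 3 fell, adjusted over the list alone too, 0.384; MICB fell from 12.3 to 6.36).

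Signs differed within some of these lists. Interferon-stimulated genes had a median of −0.08, a mean of −0.01 and an upward direction by camera, MHC class I genes −0.15, −0.01 and upward, and smooth-muscle and TGF-beta-responsive genes 0.07, −0.04 and downward (adjusted p = 0.982), where CNN1 fell from 40.5 to 17.2 FPKM. Unfolded protein and stress response genes rose in 5 of 25 cases and fell in 11, or 5 and 12 adjusted over the list alone (adjusted p = 0.24), with CRELD2 falling from 39.5 to 20.3 and DNAJB9 rising from 7.55 to 14.0. In the BCL-2 family 5 of 11 rose and 2 fell, adjusted over the list alone too (adjusted p = 0.334), with BCL2L1 from 34.5 to 52.8. Between the sorted fractions NF-kB targets had a median of 0.05, a mean of 0.00 and a downward direction (adjusted p = 0.85). Interferon-stimulated genes, not called there (0.502), were called lower without PD-L1-negative replicate 2 (0.00797) and higher without PD-L1-positive replicate 2 (0.0476), so single libraries set their direction.

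The number of genes called was compared over all splits of the libraries, a test fixed before the data were examined. Between senescent and normal cells 1 of 84 splits called as many genes, the real one, with 7099 in a fit of 2 groups and at most 6 in any other. Between the fractions 10 of 10 splits called at least the 0 of the real one, with at most 2. Against normal cells the real splits called 6066 and 6058 genes for PD-L1-negative and PD-L1-positive cells, any other split called at most 1, and 1 of 10 splits reached the real value in each. With 3 against 3 libraries there are too few splits for a share under 0.05.

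The tests of the mitosis list between the fractions were chosen only after the result was seen. The list mean per library had an exact permutation p of 0.1, the least that 3 against 3 libraries can give, and the median of 0.52 fell to 0.25 without PD-L1-negative replicate 2, so spread between libraries and a real difference cannot be told apart. Scaling was an unlikely cause, as the smallest median over 3 other scalings was 0.49 with 40 of 40 members positive. Cells like the mean of the normal libraries among the sorted PD-L1-positive cells would need a share of 8.56% for the mitosis list (95% bounds over genes 7.4 to 9.68). The 43 genes outside the cell cycle that fell at least 4-fold gave 3.02% (0.932 to 4.16). They were picked over all senescent libraries, the PD-L1-positive ones included, which favors genes low there and can make this share too low. Picked from PD-L1-negative against normal cells, 56 genes gave 4.14% (2.88 to 5.32). The bounds stayed apart with normal replicates 2 and 3 as reference, without each PD-L1-negative library and with 2 other rules for picking the genes. This bound was set after these shares were seen. It treats genes as independent, although the mitosis genes had an estimated correlation of 0.953. It replaced one on the extremes of single libraries, which was not met without PD-L1-negative replicate 2. There the lowest mitosis share was 1.98%, and the highest other share was 1.98%, or 2.85% and 3.25% by the 2 other rules. By the later bound such cells were an unlikely whole cause, but they cannot be excluded. With normal replicate 1 as reference the bounds were apart with all libraries (4.56%, 4.09 to 5.08, against 1.84%, 0.859 to 2.8) but overlapped without PD-L1-negative replicate 2 by the 2 other rules (2.63%, 2.18 to 3.31, against 1.69% with upper bounds of 2.51 and 2.48), so cells like that library and a difference between the fractions cannot be told apart.

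Explanations for the histone transcripts and for the normal libraries were weighed next, and all but the polyA test were chosen only after the result was seen. Carry-over of RNA without a polyA tail that raised small structural RNAs and histone messages alike was an unlikely cause of the histone rise. The median of these small RNAs over 46 genes was −0.06 (95% interval −0.91 to 0.85), under the bound of 1.03. They varied widely, with 1 called higher and 1 lower. Whether they track carry-over of histone messages was not tested, so carry-over of the histone messages alone cannot be excluded. The smallest histone median over 3 other scalings was 2.06. Cells like the senescent ones in normal replicate 3 would need a share of 84.9% for its mitosis genes, whereas 122 genes that rose at least 4-fold gave 7.37%. The 122 genes were picked against the mean of the normal libraries, normal replicate 3 included. That choice favors genes low in this library, so their share can be too low and does not decide how much of the spread such cells explain. The range of the mitosis list over the normal libraries was at least 1.89 with other scalings, and why these libraries differed was not tested.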
